A study of Capra hircus with 3 samples.

How the data were processed

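Liver cells of 15 female goats aged 3 to 4 years were measured in 3 groups of 5: healthy goats on the LRDS diet (Con), goats with non-alcoholic steatohepatitis on the HRDS diet (NASH) and goats of the steatohepatitis tolerance group on the HRDS diet (NASH-T). Per the labels' protocols, livers were cut up and digested with 0.25% trypsin at 37 °C for 40 min, with cells collected every 20 min, then passed through a 40 µm strainer and freed of red cells, and the 5 livers of each group were pooled. Each group therefore has 1 library and no replicate. Per the submitters' processing notes, reads were processed with Cell Ranger 7.0.0, and the values deposited for each library are UMI counts per gene and barcode. The genome build and annotation release are not given in the sources used here.

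The deposited count matrices held 27271 genes and 7485, 8731 and 9375 barcodes for Con, NASH and NASH-T, with 25506238, 31195014 and 29572158 UMIs. Every barcode already had at least 500 UMIs, so the authors' cell calling had been applied before deposit. Of the genes, 9958 carry an identifier only, and the matrices do not pair these with names. They count towards library totals, but only 2 are described. Sequencing reads were not used here.

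Cells were kept with at least 200 genes, at least 500 UMIs and at most 20% of UMIs from the 13 mitochondrially encoded genes. These limits removed 1, 0 and 2 barcodes. Doublets were called per library with Scrublet (scanpy 1.11.5, expected rate 0.06), which removed 284, 342 and 459 barcodes, or 3.79%, 3.92% and 4.90%. The kept cells numbered 7200, 8389 and 8914, with a median of 1349, 1383 and 1225 genes. Their 23752171, 29059323 and 27005297 UMIs set the precision. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components, 15 neighbours and Leiden clustering (resolution 0.8, seed 0) gave 25 clusters. All 3 libraries were clustered together without batch correction, since group and library coincide.

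Clusters were named from 20 marker sets with 233 gene names, of which 189 were in the matrices. A cluster took the class whose markers had the highest mean log2 fold over the other clusters (20 CPM added to both), unless the next class had more markers among the 10 leading genes. With equal numbers above 0 there and folds within 1 log2 unit it stayed unnamed. With fewer than 3 markers at 2-fold it also stayed unnamed, except where the class was hepatocyte. Between the T lineages the fold decided, and NK markers among the leading genes moved a cluster to NK-like. Names carry "-like" because they rest on markers alone. A cluster whose hepatocyte markers reached 0.5 of the median level of hepatocyte-like clusters, with at least 3 markers of another class at 2-fold, was called mixed and left out of every class. The marker genes were fixed beforehand, but these naming rules and the mixed rule were set once the clusters could be seen. Mixed clusters held 104, 184 and 48 cells and unnamed clusters 75, 59 and 62.

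Per library and class, UMIs were summed and divided by the class total to give CPM with exact 95% Poisson intervals. Ratios between libraries carry exact conditional binomial intervals, and shares of cells carry exact binomial intervals. A share of 0 is given with the limit that 3 counts of the total allow. All of these cover counting error only. They say nothing about variation between goats, so no test, p-value or count of differing genes is given. Where a library had 0 UMIs, the ratio is given against a floor of 3 counts as "at least". The comparisons were NASH with Con, NASH-T with Con, and NASH-T with NASH.

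A gene was named when it had a symbol, at least 50 UMIs in the class over the libraries compared, a UMI in at least 5% of cells of the higher library, a CPM of at least 20% of that in the class where it is highest, a ratio of at least 2 and an interval excluding 1. The 3 largest ratios per direction were named in the 5 largest classes, each with at least 100 cells per library. Genes that lead a cluster are pointed out where they are named, because the clusters of NASH hepatocyte-like cells hold few cells of other libraries. Ribosomal, mitochondrially encoded, haemoglobin, immunoglobulin and T cell receptor genes were not eligible.

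There were 36 gene lists with 599 names, of which 483 were in the matrices. Each list was read in the class it belongs to where that class had at least 50 cells per library, and otherwise in all cells together. A member was measured with at least 20 UMIs over both libraries, and counted as higher or lower at a ratio of at least 1.5 with an interval excluding 1. The median log2 ratio of a list was placed among 10000 random lists matched on expression in 20 bins. This percentile describes the libraries and is not a p-value. In the text, a list is given as members higher and lower of those measured, its median log2 ratio, and its percentile. Up to 4 members with the largest ratios were eligible as examples, and some of these are not reported here. The filters, markers, lists, rules for named genes and most alternatives were chosen before the data were examined.

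The share of cells with a UMI of a gene was read after thinning each cell to 1000 UMIs. This left out 90, 106 and 86 macrophage-like cells and 517, 672 and 684 T cell-like cells, and 39, 124 and 170 cells of endothelial cluster 6.

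The ratio and interval code was tested on simulated data in which 200 genes of a class were given known ratios. Class totals were drawn as Poisson counts, the model the intervals assume, so coverage near 95% was built in and checks the code only. Clumping of UMIs within cells was not simulated, so these rates need not hold for the real counts. In hepatocyte-like cells of NASH and Con, intervals covered the set ratio for 97.0% of these genes and for 95.6% of unchanged genes, and 0.897% of unchanged genes passed the 1.5-fold rule. The values were 97.0%, 95.3% and 0.716% for NASH-T and Con, and 94.0%, 95.5% and 0.846% for NASH-T and NASH. A set 2-fold ratio was recovered for 94.0%, 91.0% and 98.5% of genes in the 3 comparisons, a set 1.5-fold ratio for 37.3%, 35.8% and 41.8%. In the smaller stellate class, a 2-fold ratio was recovered for 88.1%, 85.1% and 95.5%, and 2.25%, 2.24% and 2.25% of unchanged genes passed.

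Alternatives were Leiden resolutions of 0.4 and 1.6, each library clustered on its own, doublets kept, at least 500 genes and 1000 UMIs per cell, at most 10% mitochondrial UMIs, all deposited barcodes, and shares among blood-derived cells. For expression they were scaling by the median ratio or by TMM factors (edgeR 4.0.16), thinning to 1000 UMIs, the mean of per-cell CPM, other UMI minima, a list ratio of 2, and lists read in all cells. Chosen after the data had been seen were the restriction to hepatocyte clusters filled by all libraries, the immediate early list read in macrophage-like cells, and the cells of macrophage cluster 7 that stay macrophage-like at resolution 1.6. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.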

Results

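Liver from 15 female goats aged 3 to 4 years was profiled by 3′ single-cell RNA sequencing. The groups of 5 were healthy goats on the LRDS diet (Con), goats with non-alcoholic steatohepatitis on the HRDS diet (NASH) and goats of the steatohepatitis tolerance group on the HRDS diet (NASH-T). The 5 livers of a group were pooled into 1 library, so group, pool and handling coincide. Intervals beside ratios, shares and CPM are 95% intervals of counting error only. A range beside a list median runs from the median of its members' lower limits to the median of their upper limits. Such a range is not a 95% interval of the median. After filtering, Con, NASH and NASH-T held 7200, 8389 and 8914 cells with a median of 2392.5, 2472 and 2127.5 UMIs per cell. Triplets of values are given in the order Con, NASH, NASH-T, and expression is given as CPM, the UMIs of a gene scaled to the total of its cell class.

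Hepatocyte-like cells were the largest class in every library (39.8%, 48.4% and 34.98%). Over all libraries together, T cell-like (19.6%, 16.2% and 20.5%) and macrophage-like cells (19.1%, 15.4% and 16.7%) came next. Endothelial-like (5.04%, 6.52% and 11.4%) and stellate- or fibroblast-like cells (2.60%, 4.32% and 3.44%) followed, though NK-like cells outnumbered the latter in Con and NASH-T. NK-like cells made up 3.50%, 1.81% and 3.77%, γδ T cell-like cells 2.19%, 1.30% and 2.79%, B cell-like cells 1.75%, 1.17% and 2.14%, plasma cell-like cells 1.597%, 0.584% and 1.83% and cholangiocyte-like cells 1.597%, 0.513% and 0.662%. With at least 500 genes and 1000 UMIs per cell, γδ T cell-like cells made up 0.2602%, 0.213% and 0.749%, a ratio of NASH-T to Con of 2.88 in place of 1.27. That setting names clusters anew, and only 16, 15 and 56 cells took the name, against 158, 109 and 249. T cell-like cells there numbered 994, 759 and 1284, above the 891, 687 and 1144 main T cell-like cells with at least 1000 UMIs. Cells of other classes thus became T cell-like, and the change in ratio mixes renaming with depth. Clusters without a name held 1.04%, 0.703% and 0.696%, and clusters mixing hepatocyte transcripts with those of another class held 1.44%, 2.19% and 0.538%. These shares describe what passed trypsin digestion, red cell lysis and a 40 µm strainer, and hepatocytes, cholangiocytes and stellate cells pass such steps unequally. Of the hepatocyte-like cells of Con and NASH-T, nearly all lay in clusters 0, 1 and 3 (34.8%, 49.4% and 15.1% of Con; 38.2%, 44.9% and 14.1% of NASH-T). NASH hepatocyte-like cells lay mostly in clusters 4 and 23 (36.6% and 31.4%), which held few cells of the other libraries and are therefore inseparable from the NASH library itself.

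**Figure D1:**
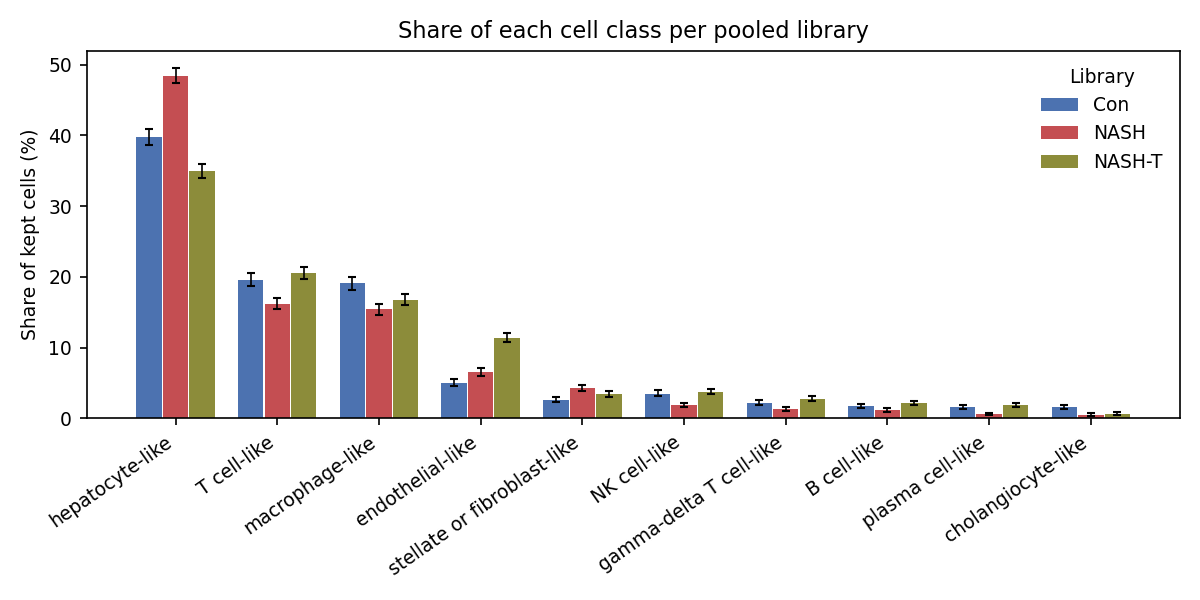
Share of kept cells in each of the 10 largest named classes per pooled library. Bars show exact 95% binomial intervals, which cover counting error only.

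The first question was how the liver of goats with steatohepatitis differed from that of healthy goats, cell class by cell class. In hepatocyte-like cells, genes of fat and cholesterol synthesis were much higher in NASH than in Con. SCD, the stearoyl-CoA desaturase, was higher by 21.1-fold (15.0 to 30.6) and FASN, the fatty acid synthase, by 14.2-fold (12.9 to 15.7). FDPS, the farnesyl diphosphate synthase of the cholesterol pathway, was higher by 5.21-fold (4.85 to 5.60). In macrophage-like cells the lipid-associated gene GPNMB was lower by 10.6-fold (ratio 0.0944, 0.0689 to 0.127). Hepatocyte-like cells took a larger share of NASH than of Con, with a ratio of 1.22 (1.16 to 1.28).

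Of the lipogenesis and triglyceride synthesis genes, 12 of 18 measured were higher in NASH hepatocyte-like cells by at least 1.5-fold and 0 were lower, with a median log2 ratio of 1.09, above all 10000 expression-matched random lists. SCD stood at 2.36, 49.9 and 17.6 CPM and FASN at 29.8, 424 and 83.5 CPM. THRSP was higher by 20.5-fold (7.78 to 76.4) and PNPLA3 by 14.5-fold (2.32 to 601), the latter against 1 UMI in Con. Of the cholesterol synthesis genes, 16 of 18 were higher and 0 lower, with a median of 1.55, again above all random lists. HMGCS1 was higher by 8.45-fold (7.14 to 10.1) and DHCR7 by 6.37-fold (4.72 to 8.77). Thinned to 1000 UMIs per cell, SCD was higher by 13.6-fold. Within clusters 0, 1 and 3 taken singly, the NASH to Con ratios were 13.5, 25.8 and 4.09 for SCD and 7.58, 11.2 and 6.91 for FASN. The median gene of this class sat at −0.14 log2 in NASH against Con, and relative to it the lipogenesis and cholesterol list medians were 1.23 and 1.70. FASN is among the genes that define cluster 23. The cholesterol list was nevertheless higher within clusters 0, 1 and 3 taken singly (medians 1.25, 1.59 and 1.20), as was the lipogenesis list (0.38, 0.87 and 0.71).

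**Figure D2:**
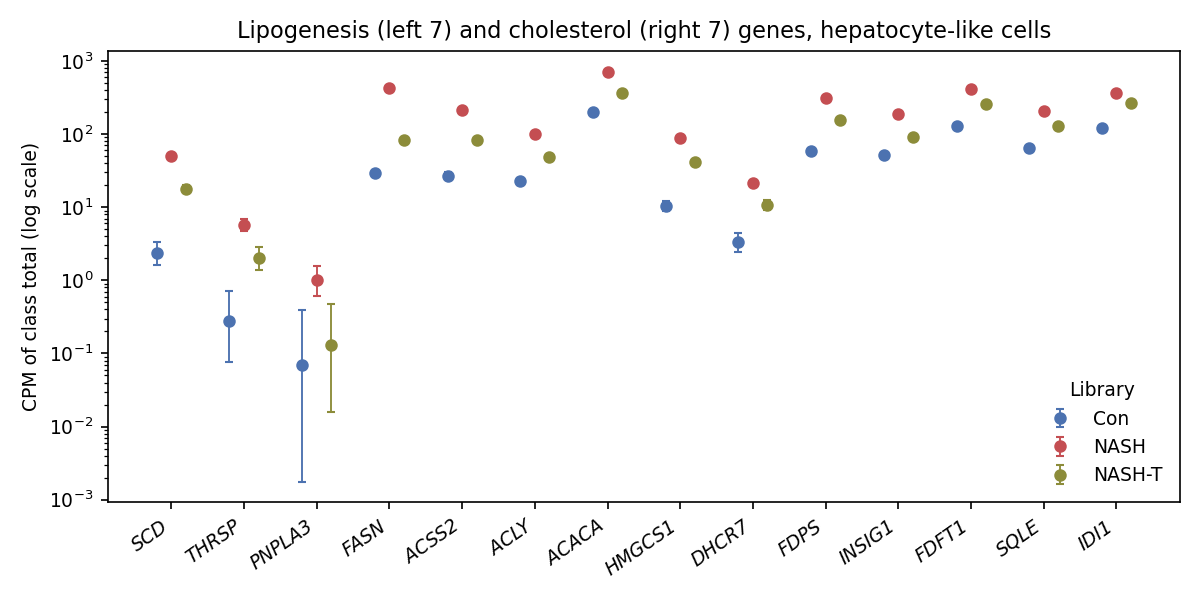
Expression of lipogenesis and cholesterol synthesis genes in hepatocyte-like cells of each pooled library, on a log scale. Bars show exact 95% Poisson intervals, which cover counting error only.

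Outside these lists, the genes that were named in hepatocyte-like cells ran in both directions. CACNA2D3, a calcium channel subunit, was higher in NASH by 17.9-fold (11.7 to 28.8), and it leads cluster 4; the ratio was 75.3 after thinning and 5.79 in the hepatocyte clusters that every library fills. RRAD, a Ras-related GTPase, was higher by 16.3-fold (9.18 to 31.9). The kinase gene PAK5 was lower by 41.5-fold (ratio 0.0241, 0.0152 to 0.0364), at 48.1, 1.16 and 2.70 CPM, and by 22.1-fold in those shared clusters. PAPPA, a protease that frees insulin-like growth factors from their binding proteins, was lower by 26.5-fold (ratio 0.0378, 0.0213 to 0.0623), and the imprinted gene NNAT by 11.6-fold (ratio 0.0859, 0.0727 to 0.101). After thinning, PAPPA was lower by 53.8-fold and NNAT by 19.5-fold. Within clusters 0, 1 and 3 the NNAT ratios were 0.00838, 0.102 and 1.14 (0.647 to 1.94 in cluster 3). The cluster 3 ratio rests on 21 NASH UMIs, and the share of its cells with an NNAT UMI was 3.93% in Con and 1.20% of 249 cells in NASH.

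The other hepatocyte programmes moved little as lists. Bile acid synthesis and transport had 2 higher and 1 lower of 16 (median 0.14, percentile 98.7). Its first enzyme, CYP7A1, was higher by 2.03-fold (1.95 to 2.12), although this gene too leads cluster 4. Within single clusters its ratio was 0.557 (0.461 to 0.671) in cluster 0, 1.197 in cluster 1, 1.19 in cluster 3, 1.15 in cluster 4 and 1.17 in cluster 23. Con held only 15 cells in cluster 4 and 4 cells in cluster 23, so the last ratios rest on few cells. CYP27A1 was lower by 1.93-fold (ratio 0.519, 0.494 to 0.545). The acute phase and complement list had 4 higher and 0 lower of 14 (median 0.13, percentile 93.5), with HAMP, which encodes hepcidin, higher by 2.11-fold (2.03 to 2.19) and FGA by 1.67-fold (1.64 to 1.70). In the cytochrome P450 and drug handling list (0 higher and 3 lower of 9, median −0.15, percentile 12.6), CYP1A1 was lower by 2.19-fold (ratio 0.456, 0.411 to 0.506). Fatty acid oxidation and ketogenesis had 2 higher and 0 lower of 20 (median −0.00, percentile 77.0); FGF21 was higher by 2.10-fold (1.85 to 2.39). The lipid droplet and uptake list had 2 higher and 2 lower of 11 (median −0.10, percentile 44.5): PLIN2 was higher by 1.61-fold (1.28 to 2.04) and ANGPTL4 lower by 3.80-fold (ratio 0.263, 0.101 to 0.614). Gluconeogenesis had 1 higher and 1 lower of 13 (median 0.02, percentile 66.6), with SDS lower by 4.20-fold (ratio 0.238, 0.144 to 0.382), and the urea cycle had 0 higher and 0 lower of 8 (median −0.18, percentile 8.64).

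In macrophage-like cells of NASH the lipid-associated list ran low. Of its 11 measured genes 6 were lower and 0 higher, with a median log2 ratio of −0.60, below all random lists. GPNMB stood at 156, 14.7 and 75.2 CPM, and the fatty acid receptor gene CD36 was lower by 4.36-fold (ratio 0.229, 0.195 to 0.268). After thinning to 1000 UMIs per cell, 6.92%, 1.01% and 2.63% of macrophage-like cells held a GPNMB UMI (9.81%, 2.08% and 5.03% unthinned, at median depths of 2713.5, 2292 and 2762 UMIs), against 0.561%, 0.146% and 0.612% of thinned T cell-like cells, whose median depths were 1160.5, 1006 and 1175.5 UMIs. GLDN was lower by 7.26-fold (ratio 0.138, 0.106 to 0.176) and MCOLN3 by 5.19-fold (ratio 0.193, 0.144 to 0.254). GPNMB, GLDN and MCOLN3 lead macrophage cluster 7, which held 35.9%, 29.3% and 21.5% of the class, so a smaller cluster 7 lowers them too. ANKRD29 was higher by 4.58-fold (3.80 to 5.56) and PID1 by 3.02-fold (2.76 to 3.32).

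Kupffer identity genes had 0 higher and 1 lower of 12 (median −0.13, percentile 1.66), the lower one being CD163 with 1.95-fold (ratio 0.512, 0.483 to 0.541). The other macrophage lists were inflammatory cytokines (0 higher and 3 lower of 14, median −0.11, percentile 8.22), interferon-stimulated genes (1 higher and 2 lower of 20, median −0.11, percentile 7.68) and endotoxin recognition (1 higher and 0 lower of 8, median 0.20, percentile 97.7). Antigen presentation (0 higher and 0 lower of 15, median 0.07, percentile 87.1) and complement C1q with scavenging (0 higher and 0 lower of 11, median −0.11, percentile 5.03) had no member called.

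Endothelial-like cells made up a larger share in NASH (ratio 1.29, 1.13 to 1.48) and so did stellate- or fibroblast-like cells (1.66, 1.39 to 1.99). With each library clustered on its own, the endothelial ratio turned to 0.241, as 422 of the 547 endothelial-like cells of NASH fell in a cluster called mixed. SYT10, a synaptotagmin gene, had 0, 155 and 5 UMIs in the endothelial class, at least 38.5-fold higher in NASH than in Con and at least 18.4-fold after thinning. In cluster 6, the larger endothelial cluster, 36 of 348 thinned NASH cells held a SYT10 UMI (10.3%, 7.35 to 14.0; 13.8% unthinned) against 0 of 240 in Con, which allows a share of up to 1.25%, and 0.291% of thinned NASH T cell-like cells. WSCD2 was higher by 4.30-fold (2.72 to 7.10). PALMD was lower by 7.16-fold (ratio 0.140, 0.0603 to 0.288), CA8 by 4.59-fold (ratio 0.218, 0.123 to 0.368) and EPHA7 by 3.56-fold (ratio 0.281, 0.159 to 0.478). The endothelial lists had 1 higher and 0 lower of 12 (median 0.22, percentile 99.4) for sinusoidal identity, 1 higher and 0 lower of 9 (median 0.19, percentile 95.3) for vascular and capillary genes, 0 higher and 2 lower of 11 (median −0.07, percentile 40.5) for interferon-stimulated genes and 1 higher and 1 lower of 10 (median 0.16, percentile 88.1) for antigen presentation.

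In stellate- or fibroblast-like cells CCN1, a matricellular gene, was higher by 8.12-fold (2.98 to 30.9), or by 4.997-fold after thinning, while CACNA1E was lower by 5.50-fold (ratio 0.182, 0.0872 to 0.352), DKK3 by 3.14-fold (ratio 0.318, 0.170 to 0.576) and PLCXD3 by 2.85-fold (ratio 0.351, 0.230 to 0.528). Extracellular matrix and fibrosis genes had 2 higher and 0 lower of 18 (median 0.08, percentile 60.0), with CCN2 higher by 3.66-fold (1.25 to 14.6) and BGN by 1.66-fold (1.07 to 2.61). The quiescence list had 1 higher and 0 lower of 10 (median −0.16, percentile 4.99). Both lists were read in cluster 21 alone. They leave out the unnamed cluster 17 (75, 59 and 62 cells), which scored 2.78 for smooth muscle and 2.57 for stellate or fibroblast markers. Its leading genes include DCN and ACTA2.

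In T cell-like cells of NASH the naive and residency list had 0 higher and 3 lower of 10 (median −0.53, percentile 0.01): ITGA1 was lower by 1.71-fold (ratio 0.585, 0.505 to 0.676) and CXCR4 by 1.88-fold (ratio 0.533, 0.275 to 0.989). Of the T cell-like cells, cluster 16, led by LEF1 and IL7R, held 36.2%, 24.5% and 29.0%, cluster 13 held 52.7%, 65.5% and 50.9%, and cluster 15 held 11.1%, 10.0% and 20.1%. The interferon-induced GTPase gene GBP5 was lower by 2.49-fold (ratio 0.401, 0.2597 to 0.605), or by 1.41-fold after thinning, and SHC3 higher by 2.86-fold (2.10 to 3.92). Other T cell lists had 2 higher and 0 lower of 15 (median 0.16, percentile 92.8) for interferon-stimulated genes, 1 higher and 1 lower of 8 (median −0.09, percentile 27.9) for cytotoxic genes and 1 higher and 1 lower of 10 (median −0.07, percentile 25.1) for checkpoint and regulatory genes. The cytotoxic list had 0 higher and 0 lower of 5 (median −0.09, percentile 37.0) in NK-like cells. B cell-like cells had 0 higher and 0 lower of 11 (median 0.20, percentile 83.7) for antigen presentation and 0 higher and 0 lower of 4 (median −0.01, percentile 54.6) for activation. The share of T cell-like cells was lower, with a ratio of 0.828 (0.768 to 0.893), as were those of macrophage-like (0.808, 0.748 to 0.872), NK-like (0.518, 0.420 to 0.636), plasma cell-like (0.366, 0.256 to 0.515) and cholangiocyte-like cells (0.321, 0.221 to 0.459). Among blood-derived cells only, the ratios were 1.08 for T cell-like and 1.05 for macrophage-like cells, so neither was lower there.

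Some genes named in non-hepatocytes moved the same way in several classes. FABP1 was higher by 4.36-fold (3.63 to 5.27) in T cell-like, 4.52-fold (3.77 to 5.44) in macrophage-like, 4.17-fold (2.99 to 5.94) in endothelial-like and 3.80-fold (2.52 to 5.94) in stellate-like cells, and hepatocyte-like cells themselves held only 73.6, 292 and 125 CPM against 81.7, 356 and 135 CPM in T cell-like cells. HAMP was higher by 3.42-fold (2.75 to 4.27) in T cell-like and 3.79-fold (2.28 to 6.63) in stellate-like cells, next to 243, 511 and 482 CPM in hepatocyte-like cells. ITIH4 and IGFBP2, lower in T cell-like cells by 2.79-fold (ratio 0.358, 0.243 to 0.516) and 2.33-fold (ratio 0.429, 0.277 to 0.650), were lower in hepatocyte-like cells as well (350.2, 247 and 305 CPM and 172, 89.0 and 77.5 CPM). In NASH, a FABP1 UMI was found in 30.9% of T cell-like, 34.3% of macrophage-like, 32.2% of endothelial-like and 35.1% of stellate-like cells. In Con the shares of these classes were 9.09%, 9.88%, 10.5% and 12.3%. Such like shares in classes of unlike depth are what free RNA would give. No background of empty droplets was measured, so free RNA was not separated from expression for these genes. The list of hepatocyte transcripts had 4 higher and 0 lower of 13 (median 0.50, percentile 100) over all cells. These include the hepatocyte-like cells, whose share was larger in NASH, so this list does not read the other classes alone.

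Over all cells the median gene sat at −0.17 log2, and the lists read there mix cell classes. Relative to it the medians of the bile duct, neutrophil and proliferation lists below were −0.54, −1.16 and −0.43. Bile duct genes had 0 higher and 6 lower of 12 (median −0.70, percentile 0.675), with TFF3 lower by 3.72-fold (ratio 0.269, 0.160 to 0.436) and CFTR by 3.69-fold (ratio 0.271, 0.241 to 0.303), which goes with the smaller cholangiocyte share. Neutrophil granule and attraction genes had 1 higher and 5 lower of 8 (median −1.32, percentile 0): IL1R2 was lower by 3.83-fold (ratio 0.261, 0.168 to 0.395) and LTF higher by 3.06-fold (2.42 to 3.89). No main cluster took the neutrophil name, so in every comparison this list is not a reading of neutrophils. Proliferation genes had 0 higher and 6 lower of 13 (median −0.60, percentile 0.83), with MCM5 lower by 2.45-fold (ratio 0.409, 0.257 to 0.639). The rest were apoptosis and p53 response (1 higher and 2 lower of 12, median −0.29, percentile 10.1), antioxidant and metallothionein (0 higher and 2 lower of 14, median −0.21, percentile 17.8), immediate early response (1 higher and 1 lower of 17, median −0.13, percentile 63.6), heat shock (2 higher and 0 lower of 9, median −0.01, percentile 86.1), unfolded protein response (0 higher and 0 lower of 13, median −0.15, percentile 43.3), glycolysis and hypoxia (0 higher and 3 lower of 17, median −0.13, percentile 60.0) and oxidative phosphorylation (0 higher and 0 lower of 16, median −0.11, percentile 73.3). Of the erythrocyte transcripts, 0 were measured in any comparison.

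The next question was how goats of the tolerance group differed from healthy goats. Hepatocyte-like cells of NASH-T also had higher transcripts of lipid synthesis genes, with smaller ratios than NASH: SCD was higher than in Con by 7.46-fold (5.21 to 11.0), or by 3.43-fold after thinning, FASN by 2.80-fold (2.51 to 3.13) and HMGCS1 by 4.00-fold (3.34 to 4.81). In macrophage-like cells CD36 was lower by 6.18-fold (ratio 0.162, 0.137 to 0.190), while the immediate early gene FOS was higher by 5.30-fold (4.55 to 6.19) and the interferon-stimulated gene ISG15 by 3.49-fold (2.76 to 4.46). Endothelial-like cells made up a larger share, with a ratio of 2.26 (2.00 to 2.55), and expressed MMRN1, which encodes multimerin 1, at 9.84, 2.09 and 413 CPM.

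Lipogenesis genes in hepatocyte-like cells had 9 higher and 2 lower of 17 (median 0.67, percentile 100), and cholesterol synthesis genes had 12 higher and 0 lower of 18 (median 0.81, percentile 100). The SCD ratio was 5.35 (3.08 to 9.94) within cluster 0, 13.5 (7.497 to 26.6) within cluster 1 and 1.23 (0.367 to 4.10) within cluster 3, the last from 7 UMIs in Con and 7 in NASH-T. THRSP was higher by 7.34-fold (2.59 to 28.6), ME1 by 3.26-fold (2.66 to 4.01) and ACSS2 by 3.09-fold (2.76 to 3.47). DHCR7 was higher by 3.20-fold (2.30 to 4.51) and FDPS by 2.60-fold (2.40 to 2.81). Fatty acid oxidation and ketogenesis had 4 higher and 0 lower of 20 (median 0.13, percentile 99.8), with HADHA higher by 1.54-fold (1.42 to 1.69). PDK4 was higher by 1.77-fold (1.69 to 1.86), though it belongs to the genes that define cluster 0. PLIN2, which coats lipid droplets, was higher by 3.88-fold (3.14 to 4.83) in a droplet and uptake list with 2 higher and 0 lower of 11 (median 0.03, percentile 84.9).

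The acute phase and complement list had 5 higher and 0 lower of 14 (median 0.40, percentile 100), with HAMP higher by 1.99-fold (1.91 to 2.07) and LBP, the lipopolysaccharide-binding protein gene, by 1.79-fold (1.73 to 1.86). Urea cycle genes had 0 higher and 2 lower of 8 (median −0.29, percentile 1.04): ASL was lower by 1.58-fold (ratio 0.633, 0.588 to 0.681) and ASS1 by 1.52-fold (ratio 0.659, 0.629 to 0.691). The cytochrome P450 list had 0 higher and 1 lower of 9 (median −0.35, percentile 0.325), bile acid genes had 0 higher and 1 lower of 16 (median 0.08, percentile 95.9) and gluconeogenesis genes had 0 higher and 0 lower of 13 (median 0.03, percentile 71.6). Among single genes, the cation channel gene TRPC6 was higher by 5.80-fold (5.25 to 6.41), with ratios of 3.24, 13.1 and 3.93 in clusters 0, 1 and 3, and USH1C by 4.70-fold (3.77 to 5.92). PTPRD, a receptor tyrosine phosphatase gene, was lower by 75.7-fold (ratio 0.0132, 0.00805 to 0.0205), at 99.7, 32.2 and 1.32 CPM, and by 114-fold after thinning. PAK5 was lower by 17.8-fold (ratio 0.0561, 0.0399 to 0.0769) and NNAT by 8.31-fold (ratio 0.120, 0.102 to 0.141), in the same direction as in NASH. The NNAT ratios were 0.0215, 0.228 and 0.128 within clusters 0, 1 and 3.

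In macrophage-like cells the lipid-associated list had 0 higher and 6 lower of 13 (median −0.58, percentile 0), with CTSL lower by 3.16-fold (ratio 0.317, 0.102 to 0.842), ATP6V0D2 by 2.97-fold (ratio 0.337, 0.108 to 0.906) and GPNMB by 2.08-fold (ratio 0.481, 0.420 to 0.550). Within cluster 7, which held 35.9% of the class in Con and 21.5% in NASH-T, the GPNMB ratio was 0.831 (0.724 to 0.953), and in cluster 10 it was 2.00 (0.745 to 6.25). The CD36 ratio was 0.191 in cluster 7 and 0.603 in cluster 10, and the FOS ratio 2.11 and 6.86. The lipid-associated list was not robust to thinning: at 1000 UMIs per cell its median was −0.12. Median depths were close before thinning, at 2713.5 UMIs in Con and 2762 in NASH-T, and the cause of the change was not tested. Interferon-stimulated genes had 7 higher and 0 lower of 21 (median 0.41, percentile 100), with IFIT1 higher by 2.51-fold (1.76 to 3.64) and IRF7 by 1.88-fold (1.21 to 2.99). Antigen presentation had 3 higher and 0 lower of 15 (median 0.29, percentile 100), with CD80 higher by 1.92-fold (1.66 to 2.23) and CD86 by 1.84-fold (1.73 to 1.97). Inflammatory cytokines had 3 higher and 1 lower of 14 (median 0.31, percentile 99.99): CXCL8 was higher by 3.26-fold (2.11 to 5.19), TNF by 1.57-fold (1.20 to 2.08) and IL10 by 1.67-fold (1.40 to 1.99), while CCL8 was lower by 3.31-fold (ratio 0.302, 0.196 to 0.456). Endotoxin recognition had 2 higher and 0 lower of 9 (median 0.26, percentile 99.0), with TLR4 higher by 1.84-fold (1.62 to 2.09). Kupffer identity had 2 higher and 1 lower of 12 (median 0.10, percentile 95.8) and complement C1q 0 higher and 0 lower of 11 (median −0.03, percentile 34.1). UBE2QL1 was higher by 5.45-fold (3.61 to 8.53), or by 3.45-fold after thinning, and TMPRSS11E by 4.70-fold (3.07 to 7.45); MALRD1 was lower by 4.03-fold (ratio 0.248, 0.213 to 0.287) and EFCAB6 by 3.77-fold (ratio 0.265, 0.164 to 0.415).

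**Figure D3:**
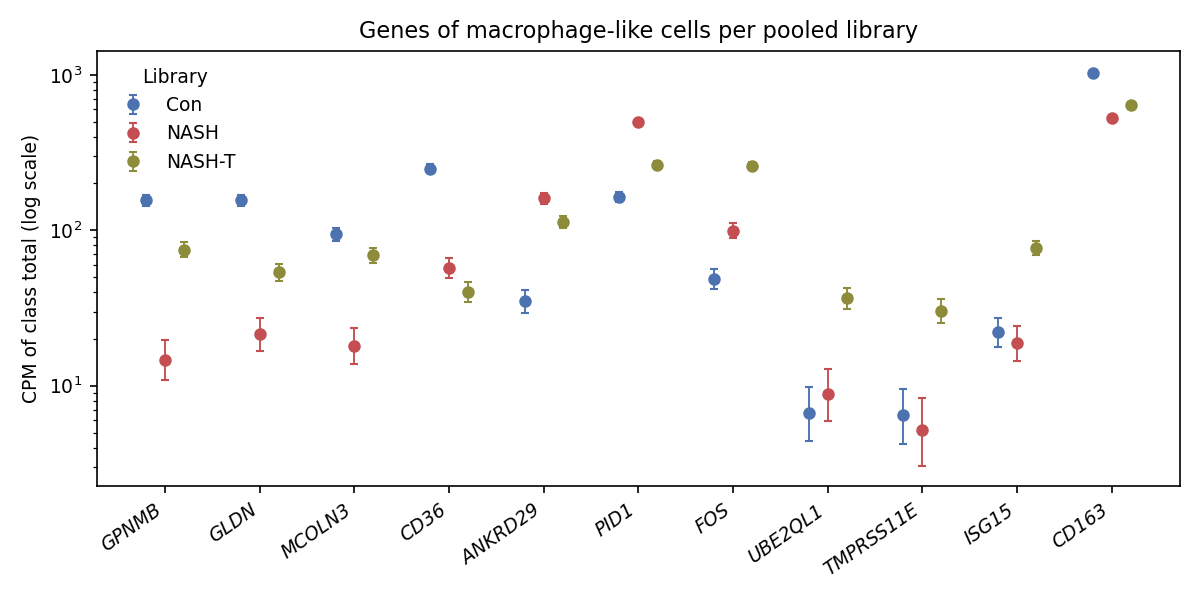
Expression of genes named in macrophage-like cells in each pooled library, on a log scale. Bars show exact 95% Poisson intervals, which cover counting error only.

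In endothelial-like cells MMRN1 was higher by 42.0-fold (20.3 to 105), from 7, 2 and 817 UMIs. Within cluster 6, 157 of 721 thinned NASH-T cells held a MMRN1 UMI (21.8%, 18.8 to 24.97; 26.4% unthinned), against 0 of 240 in Con and 0 of 348 in NASH, which allow shares of up to 1.25% and 0.862%. In thinned T cell-like cells the shares were 0.337% in Con and 0.0874% in NASH-T, and 0 in NASH, which allows up to 0.437%. RND1 was higher by 5.96-fold (2.80 to 15.2) and ISG15 by 4.83-fold (2.25 to 12.3). PALMD was lower by 4.77-fold (ratio 0.210, 0.127 to 0.341), LSP1 by 3.94-fold (ratio 0.254, 0.161 to 0.397) and ADGRV1 by 3.32-fold (ratio 0.301, 0.214 to 0.422). Interferon-stimulated genes had 4 higher and 0 lower of 17 (median 0.52, percentile 99.97), sinusoidal identity 3 higher and 1 lower of 12 (median 0.26, percentile 99.7), antigen presentation 3 higher and 1 lower of 11 (median 0.31, percentile 97.2) and vascular genes 2 higher and 0 lower of 9 (median 0.19, percentile 94.1). LYVE1, a sinusoidal hyaluronan receptor gene, was higher by 1.73-fold (1.46 to 2.05) and the Wnt agonist gene RSPO3 lower by 2.26-fold (ratio 0.443, 0.315 to 0.624).

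Stellate- or fibroblast-like cells of NASH-T had PCDH15 higher by 45.5-fold (7.90 to 1824) against 1 UMI in Con, or by 5.33-fold after thinning, 15.5-fold as the mean of per-cell CPM, 15.1-fold with at least 500 genes and 1000 UMIs, and 1.76-fold with doublets kept. THBS1 was higher by 3.20-fold (1.54 to 7.46) and EPB41L4A by 3.06-fold (2.11 to 4.55). PLXDC2 was lower by 3.35-fold (ratio 0.299, 0.186 to 0.469), RASEF by 3.12-fold (ratio 0.321, 0.231 to 0.441) and MOB3B by 2.79-fold (ratio 0.359, 0.251 to 0.508). Matrix and fibrosis genes had 3 higher and 0 lower of 16 (median 0.23, percentile 97.2) and quiescence genes 1 higher and 0 lower of 11 (median 0.03, percentile 61.4). In T cell-like cells ASPH was higher by 4.02-fold (3.06 to 5.36), or by 2.49-fold as the mean of per-cell CPM, ZNF25 by 2.36-fold (1.64 to 3.45) and ARHGAP5 by 2.35-fold (1.99 to 2.79). SLC22A15 was lower by 2.35-fold (ratio 0.426, 0.316 to 0.571), IL1RL1 by 2.09-fold (ratio 0.477, 0.388 to 0.586) and NCAPD2 by 2.06-fold (ratio 0.484, 0.341 to 0.684). The T cell lists had 4 higher and 0 lower of 18 (median 0.26, percentile 99.5) for interferon-stimulated genes, 2 higher and 0 lower of 10 (median −0.10, percentile 17.0) for naive and residency genes, 0 higher and 1 lower of 10 (median −0.23, percentile 2.64) for checkpoint genes and 0 higher and 1 lower of 8 (median −0.01, percentile 52.0) for cytotoxic genes.

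Over all cells, immediate early genes had 7 higher and 0 lower of 17 (median 0.55, percentile 100): FOS was higher by 3.41-fold (3.12 to 3.72), DUSP1 by 2.52-fold (2.37 to 2.68), KLF2 by 2.46-fold (2.27 to 2.67) and JUN by 2.24-fold (2.06 to 2.43). Dissociation induces these genes, and the heat shock list, which it also induces, had 0 higher and 1 lower of 9 (median 0.12, percentile 90.9). Proliferation genes had 0 higher and 4 lower of 13 (median −0.32, percentile 1.86). Hepatocyte transcripts had 1 higher and 0 lower of 13 (median 0.32, percentile 100), neutrophil genes 2 higher and 1 lower of 10 (median 0.11, percentile 78.8), oxidative phosphorylation 1 higher and 0 lower of 16 (median 0.17, percentile 99.4) and glycolysis 1 higher and 0 lower of 17 (median 0.11, percentile 95.4). Apoptosis had 1 higher and 0 lower of 12 (median 0.06, percentile 84.1), antioxidant genes 1 higher and 0 lower of 13 (median −0.02, percentile 41.4) and the unfolded protein response 0 higher and 1 lower of 13 (median −0.06, percentile 26.0). Bile duct genes, read in cholangiocyte-like cells here, had 0 higher and 1 lower of 7 (median −0.29, percentile 9.21). In B cell-like cells antigen presentation had 2 higher and 1 lower of 13 (median 0.21, percentile 92.1) and activation 1 higher and 0 lower of 4 (median 0.15, percentile 77.2); in NK-like cells the cytotoxic list had 0 higher and 0 lower of 6 (median 0.06, percentile 64.4). JCHAIN was at 12.2, 9.67 and 31.8 CPM in hepatocyte-like and 21.2, 26.1 and 96.6 CPM in T cell-like cells. Hepatocyte-like and macrophage-like cells took smaller shares of NASH-T, with ratios of 0.878 (0.835 to 0.924) and 0.875 (0.813 to 0.942), as did cholangiocyte-like cells (0.414, 0.297 to 0.572); T cell-like (1.05, 0.978 to 1.12) and NK-like cells (1.08, 0.912 to 1.27) did not differ beyond counting error.

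The last question was what separated the tolerance group from the goats with steatohepatitis on the same diet. Hepatocyte-like cells of NASH-T had lower transcripts of lipid synthesis genes than those of NASH, with FASN lower by 5.08-fold (ratio 0.197, 0.185 to 0.209), SCD by 2.83-fold (ratio 0.354, 0.308 to 0.405) and HMGCS1 by 2.11-fold (ratio 0.473, 0.431 to 0.519). In the hepatocyte clusters that every library fills, FASN was lower by 3.39-fold. Their PLIN2 was higher by 2.41-fold (2.06 to 2.83). GPNMB in macrophage-like cells was higher by 5.10-fold (3.76 to 7.05), or by 3.33-fold as the mean of per-cell CPM, and ISG15 by 4.12-fold (3.13 to 5.50). MMRN1 in endothelial-like cells was higher by 197-fold (54.4 to 1631), against 2 UMIs in NASH, or by 59.5-fold after thinning and 374-fold as the mean of per-cell CPM. SYT10 was lower by 64.2-fold (ratio 0.0156, 0.00499 to 0.0371).

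Lipogenesis genes had 0 higher and 8 lower of 18 (median −0.50, percentile 0), and cholesterol synthesis genes 0 higher and 10 lower of 18 (median −0.64, percentile 0). PNPLA3 was lower by 7.65-fold (ratio 0.131, 0.0148 to 0.538), THRSP by 2.79-fold (ratio 0.359, 0.233 to 0.537), FDPS by 2.01-fold (ratio 0.498, 0.475 to 0.523) and INSIG1, a feedback regulator of sterol synthesis, by 2.05-fold (ratio 0.487, 0.457 to 0.518). Fatty acid oxidation and ketogenesis had 2 higher and 1 lower of 20 (median 0.16, percentile 99.9): HADHB was higher by 1.76-fold (1.62 to 1.92) and PDK4, a gene of cluster 0, by 2.24-fold (2.13 to 2.34), while FGF21 was lower by 1.65-fold (ratio 0.606, 0.541 to 0.679). The lipid droplet and uptake list had 2 higher and 1 lower of 10 (median 0.07, percentile 79.0), with CD36 higher by 1.80-fold (1.40 to 2.32). CYP7A1, a gene of cluster 4, was lower by 2.39-fold (ratio 0.419, 0.401 to 0.437). Its ratios were 0.732, 0.806 and 0.722 within clusters 0, 1 and 3, and 0.966 in cluster 4, where NASH-T held 60 cells. In cluster 23 NASH-T held 0 CYP7A1 UMIs in 27 cells, against 263 CPM in NASH. Also lower was the bile salt export pump gene ABCB11, by 1.54-fold (ratio 0.649, 0.638 to 0.662), in a bile acid list with 0 higher and 2 lower of 16 (median −0.09, percentile 13.1). SDS was higher by 2.99-fold (1.82 to 5.06) in a gluconeogenesis list with 1 higher and 0 lower of 13 (median 0.00, percentile 62.0). The acute phase list had 0 higher and 0 lower of 14 (median 0.06, percentile 90.5), the cytochrome P450 list 0 higher and 0 lower of 9 (median 0.06, percentile 77.5) and the urea cycle 0 higher and 0 lower of 8 (median −0.05, percentile 30.97).

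Of the genes that were named in hepatocyte-like cells, the largest differences were the higher PAPPA, by 35.4-fold (21.6 to 62.6), and TRPC6, by 34.5-fold (28.4 to 42.2). In the clusters that every library fills, TRPC6 was higher by 17.6-fold, and by 41.1-fold, 10.3-fold and 14.6-fold in clusters 0, 1 and 3 taken singly. In NASH-T both stood above Con: PAPPA, at 21.3, 0.806 and 28.6 CPM, was higher than in Con by 1.34-fold (1.15 to 1.55), and TRPC6 stood at 32.1, 5.39 and 186 CPM. FBN2, a fibrillin gene, was higher by 17.4-fold (14.9 to 20.4). CACNA2D3, of cluster 4, was lower by 11.5-fold (ratio 0.0866, 0.06004 to 0.121), with a ratio of 0.250 in those shared clusters, and the mitochondrial citrate carrier gene SLC25A1 by 5.55-fold (ratio 0.180, 0.132 to 0.242).

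In macrophage-like cells of NASH-T interferon-stimulated genes had 12 higher and 0 lower of 21 (median 0.70, percentile 100) and inflammatory cytokines 4 higher and 0 lower of 14 (median 0.35, percentile 100), with CXCL8 higher by 5.47-fold (3.06 to 10.6). Kupffer identity had 1 higher and 0 lower of 12 (median 0.30, percentile 100), the lipid-associated list 2 higher and 0 lower of 11 (median 0.28, percentile 99.9) and antigen presentation 3 higher and 0 lower of 15 (median 0.13, percentile 99.1), with IFI30 higher by 2.22-fold (1.97 to 2.51) and CD80 by 2.03-fold (1.73 to 2.39). Complement C1q had 0 higher and 0 lower of 11 (median 0.14, percentile 98.6) and endotoxin recognition 1 higher and 0 lower of 8 (median 0.09, percentile 84.2). C11orf65 was higher by 6.39-fold (4.06 to 10.6) and TMPRSS11E by 5.81-fold (3.50 to 10.3). The potassium channel gene KCNH5 was lower by 4.82-fold (ratio 0.207, 0.162 to 0.263) and TXLNB by 3.22-fold (ratio 0.311, 0.204 to 0.465).

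In endothelial-like cells interferon-stimulated genes had 11 higher and 0 lower of 17 (median 0.93, percentile 100): IFIT3 was higher by 6.999-fold (1.77 to 60.5), ISG15 by 5.67-fold (2.76 to 13.5), and CXCL10, with 27, 0 and 69 UMIs, by at least 11.1-fold. MDGA2 was higher by 8.98-fold (5.60 to 15.3) and CD274, which encodes PD-L1, by 6.14-fold (2.86 to 15.7). ASTN2 was lower by 4.60-fold (ratio 0.217, 0.117 to 0.388), or by 7.12-fold after thinning, and the guidance receptor gene ROBO2 by 3.99-fold (ratio 0.251, 0.1997 to 0.313). Antigen presentation had 2 higher and 0 lower of 12 (median 0.29, percentile 95.1), vascular genes 1 higher and 0 lower of 9 (median 0.12, percentile 88.3) and sinusoidal identity 0 higher and 1 lower of 12 (median 0.00, percentile 62.8). The endothelial share was larger, with a ratio of 1.75 (1.57 to 1.94), and of 7.66 with each library clustered on its own. The latter ratio leaves out 422 of the 547 endothelial-like cells of NASH, which fell in a cluster called mixed in that setting.

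Stellate- or fibroblast-like cells of NASH-T had more RBFOX1, by 8.41-fold (4.02 to 20.3) or by 14.1-fold after thinning, DLK1, by 5.37-fold (2.60 to 12.5), and PCDH15, by 4.76-fold (2.70 to 8.97), or by 1.44-fold with doublets kept. RRAD was lower by 5.35-fold (ratio 0.187, 0.0761 to 0.4004) and adrenomedullin, ADM, by 4.11-fold (ratio 0.243, 0.140 to 0.405), or by 1.98-fold with doublets kept. Matrix genes had 3 higher and 1 lower of 18 (median 0.18, percentile 98.0), with CCN2 lower by 5.47-fold (ratio 0.183, 0.0459 to 0.535), and quiescence genes 0 higher and 0 lower of 11 (median 0.18, percentile 96.5). In T cell-like cells the naive and residency list had 3 higher and 0 lower of 10 (median 0.54, percentile 100), with KLF2 higher by 2.31-fold (1.75 to 3.09) and LEF1, of cluster 16, by 1.74-fold (1.63 to 1.85). KLF2 is also in the immediate early list, whose genes dissociation induces. GBP2 was higher by 2.52-fold (1.80 to 3.60), GBP5 by 2.31-fold (1.55 to 3.53), or by 1.07-fold after thinning, and ASPH by 2.40-fold (1.89 to 3.07); PHACTR1 was lower by 2.84-fold (ratio 0.352, 0.315 to 0.394) and SHC3 by 2.46-fold (ratio 0.406, 0.310 to 0.530). Interferon-stimulated genes in T cell-like cells had 4 higher and 0 lower of 17 (median 0.01, percentile 56.3), checkpoint genes 0 higher and 1 lower of 9 (median 0.08, percentile 83.7) and cytotoxic genes 0 higher and 0 lower of 8 (median −0.06, percentile 31.9).

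FABP1 ran the other way from the first comparison: it was lower by 2.64-fold (ratio 0.378, 0.329 to 0.435) in T cell-like, 2.75-fold (ratio 0.364, 0.314 to 0.420) in macrophage-like and 3.48-fold (ratio 0.287, 0.201 to 0.403) in stellate-like cells, and by 2.34-fold (ratio 0.427, 0.405 to 0.450) in hepatocyte-like cells. Over all cells the median gene sat at 0.11 log2, and relative to it the medians of the immediate early and neutrophil lists were 0.51 and 0.87. Immediate early genes had 8 higher and 1 lower of 17 (median 0.61, percentile 99.99), with FOS higher by 4.18-fold (3.83 to 4.57), FOSB by 4.04-fold (2.85 to 5.85) and DUSP1 by 2.96-fold (2.79 to 3.15). Neutrophil genes had 5 higher and 0 lower of 9 (median 0.97, percentile 99.9), with CXCL8 higher by 8.15-fold (4.65 to 15.4). CXCL8 was also higher in macrophage-like cells, and no cluster was named neutrophil-like. Bile duct genes had 4 higher and 0 lower of 11 (median 0.23, percentile 54.1), glycolysis and hypoxia 4 higher and 0 lower of 17 (median 0.35, percentile 98.0), apoptosis 3 higher and 0 lower of 12 (median 0.36, percentile 97.1) and proliferation 2 higher and 0 lower of 13 (median 0.13, percentile 37.2). Antioxidant genes had 3 higher and 1 lower of 14 (median 0.07, percentile 37.7), heat shock 0 higher and 1 lower of 9 (median 0.07, percentile 33.4), the unfolded protein response 0 higher and 0 lower of 13 (median 0.12, percentile 54.7), oxidative phosphorylation 1 higher and 0 lower of 16 (median 0.21, percentile 82.1) and hepatocyte transcripts 0 higher and 1 lower of 13 (median −0.19, percentile 5.52). In NK-like cells the cytotoxic list had 0 higher and 0 lower of 5 (median 0.23, percentile 87.1); in B cell-like cells antigen presentation had 2 higher and 1 lower of 12 (median 0.04, percentile 61.2) and activation 1 higher and 0 lower of 4 (median 0.32, percentile 81.9).

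Hepatocyte-like cells took a smaller share in NASH-T (ratio 0.722, 0.689 to 0.757) and so did stellate-like cells (0.798, 0.683 to 0.932). T cell-like (1.27, 1.18 to 1.36), NK-like (2.08, 1.71 to 2.54) and plasma cell-like cells (3.13, 2.26 to 4.40) took larger shares, macrophage-like cells slightly so (1.08, 1.01 to 1.17), and cholangiocyte-like cells did not differ beyond counting error (1.29, 0.857 to 1.960). Among blood-derived cells only, the ratios were 0.978 for T cell-like and 0.837 for macrophage-like cells, so neither was larger there. The γδ T cell-like ratio of 2.15 became 3.52 with at least 500 genes and 1000 UMIs per cell. That value rests on 15 cells of NASH and 56 of NASH-T, and clusters were named anew there.

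**Figure D4:**
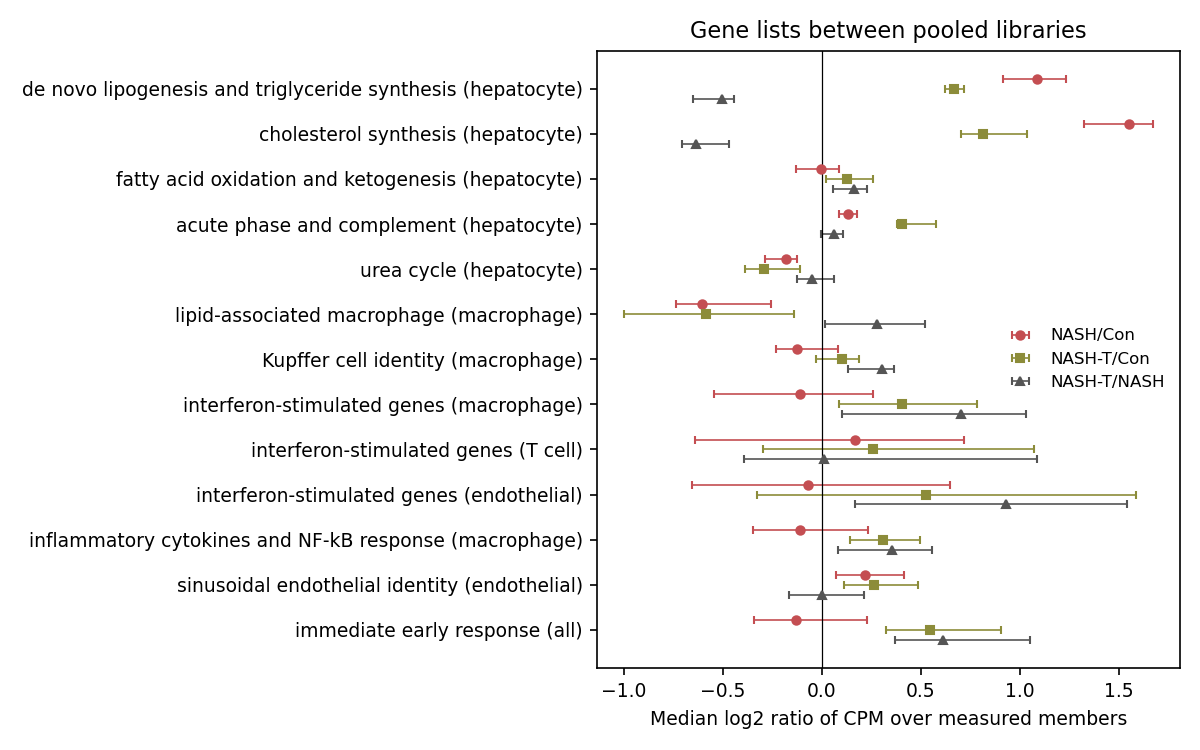
Median log2 ratio of 11 of the gene lists in the class each is read in, for the 3 comparisons. Bars run from the median of the members’ lower 95% limits to the median of their upper limits, counting error only.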

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

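The tests in this part were chosen after the results had been seen, except the tests of depth by thinning of the cholesterol and immediate early lists, whose readings were fixed beforehand. Group, pool and handling coincide in these libraries, so no test here can separate a response of the goats from a difference between pools.

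In hepatocyte-like cells, cholesterol and fatty acid synthesis genes were higher in NASH than in Con. A different mix of hepatocyte clusters could raise them, but within the shared clusters the cholesterol median stayed at 1.20 or more (0.71 to 1.64 in cluster 3), which excludes cluster mix as the whole cause. For lipogenesis the lowest cluster median was 0.38 (0.23 to 0.61, cluster 0) and the macrophage-like median 0.32 (−0.07 to 0.68), so cluster mix, free RNA and a shared shift stay open there. For cholesterol, medians of 0.18 (−0.35 to 0.60) in macrophage-like and 0.11 in T cell-like cells argue against free RNA or a shift shared by every cell. These ranges are not intervals of the median, so they do not exclude either outright. A shift shared with endothelial-like (0.81, −0.14 to 1.58) and stellate-like cells (1.00, −0.19 to 2.27) stays open. Depth was excluded as the whole cause by medians of 1.49 (1.21 to 1.80) for cholesterol and 0.91 (0.69 to 1.03) for lipogenesis after thinning. Release of the sterol-sensing factor SREBP2 is a hypothesis that staining of nuclear SREBP2 in separate livers of both groups would test.

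GPNMB and CD36 were lower in NASH than in Con macrophage-like cells. A smaller share of macrophage cluster 7 was excluded as the whole cause, since within that cluster the ratios were 0.0998 (0.0706 to 0.137) for GPNMB and 0.232 (0.192 to 0.278) for CD36. Cluster 7 held a part that becomes plasmacytoid dendritic-like at resolution 1.6 (37.9%, 62.4% and 45.9% of it), and in the rest the ratios were 0.189 (0.130 to 0.268) for GPNMB, so that this mix carries part of its difference, and 0.192 (0.137 to 0.262) for CD36, which excludes it as the whole cause of either. The CD36 test first took the higher ratio of the macrophage clusters, 0.624 (0.433 to 0.891, cluster 10), which decided nothing, and was replaced by the cluster where CD36 is highest. The share of cells with GPNMB had a ratio of 0.146 (0.0726 to 0.268) and the level per positive cell one of 0.658, so fewer positive cells at a like level could account for much of the difference, and the test did not settle it; staining for GPNMB beside a pan-macrophage marker, goat by goat, would tell these apart.

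In NASH-T, immediate early, interferon-stimulated and mitochondrially encoded RNA was higher than in Con. A general stress response to dissociation remains possible: the heat shock median in macrophage-like cells was 0.12 (−0.15 to 0.36) beside 0.71 for immediate early genes, in endothelial-like cells 0.46 (0.06 to 0.86) beside 0.73, in hepatocyte-like cells −0.12 (−0.37 to 0.04) beside 0.33 and in NK-like cells −0.05 (−0.91 to 0.79), and the thinned immediate early median of 0.65 (0.17 to 1.11) missed the lower limit of 0.2 set for excluding depth. For interferon-stimulated genes, free RNA was excluded only as the whole cause of the excess in macrophage-like cells. That excess was 1.58 UMIs per cell, against 0.165 (−0.00962 to 0.340) in stellate-like cells. The excess of 0.284 (0.209 to 0.358) in T cell-like cells lies below the upper limit in stellate-like cells, so the test cannot exclude free RNA there. In NK-like cells the excess was −0.0298 (−0.228 to 0.169). The stellate-like test replaced an undecided one, the lowest ISG15 ratio of the 5 main classes, 0.669 (0.154 to 2.91). For mitochondrially encoded RNA, free RNA was excluded as the whole cause. Its rise in T cell-like cells was 13.2 times that in macrophage-like cells, beside a depth ratio of 2.35. Fixing tissue before dissociation would test the stress reading.

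TRPC6 in hepatocyte-like cells was 34.5-fold higher in NASH-T than in NASH, while it was 5.95-fold lower in NASH than in Con, with NASH to Con ratios of 0.0788, 1.27 (0.879 to 1.81) and 0.269 in clusters 0, 1 and 3. FBN2 ran the same way, 17.4-fold higher in NASH-T than in NASH and 4.24-fold lower in NASH than in Con. MDGA2 in endothelial-like cells was 8.98-fold higher in NASH-T than in NASH and 2.91-fold lower in NASH than in Con. Mitochondrially encoded RNA made up 1.29% of UMIs in T cell-like cells of NASH-T, against 0.484% in Con and 0.635% in NASH. The unnamed gene ENSCHIG00000004312 stood at 43.2 CPM in NASH hepatocyte-like cells, against 0.556 in Con and 1 UMI in NASH-T. ENSCHIG00000015428 stood at 36.4 CPM there, against 0.695 in Con and 6.91 in NASH-T. Apart from free RNA for the mitochondrially encoded RNA, no cause of these 6 differences was tested.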

How the results depend on the processing

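No paired analysis was possible because each group is 1 pooled library. The leading lists here (lipogenesis, cholesterol, lipid-associated macrophage, interferon-stimulated in macrophage-like cells, immediate early) were picked of 36 after their values were seen. Values without an interval are ratios of shares or median log2 ratios, with the main value in parentheses. Where no reason is given, the cause was not tested. A value is called reversed when the main interval or range excluded no difference and the value falls on the other side of it. Where the main interval or range included no difference, a change of side is not counted as reversed. The counting error of the new value was not weighed, so a reversed value near no difference can mean only that the difference is gone.

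With each library clustered on its own, share ratios were 0.936 for NASH-T to Con hepatocyte-like cells (0.878); 0.985 for NASH to Con (0.828) and 1.06 for NASH-T to NASH T cell-like cells (1.27); 0.616 (0.808), 0.782 (0.875) and 1.27 (1.08) for macrophage-like cells in the order of the report; and 0.241 (1.29, so reversed), 1.85 (2.26) and 7.66 (1.75) for endothelial-like cells. In NASH alone 422 of the 547 endothelial-like cells fell in a cluster called mixed, together with 175 cells called mixed before, and 0 NK- or γδ T-like cells were named, so those ratios have no value. At 500 genes and 1000 UMIs T cell-like ratios were 0.667 for NASH to Con and 1.59 for NASH-T to NASH, these cells being shallow. Among blood-derived cells point values reversed in the same comparisons, to 1.08 and 0.978 for T cell-like and to 1.05 and 0.837 for macrophage-like cells. Hepatocyte-like, cholangiocyte-like, endothelial-like, stellate-like, mixed and unnamed cells no longer enter that total. The macrophage ratio of NASH-T to NASH was 1.20 at resolution 0.4, at 1.6 and with doublets kept.

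For NASH against Con, the lipogenesis median was 0.91 thinned and 0.57 in shared hepatocyte clusters (1.09), and the cholesterol median 1.70 by median-ratio and 1.69 by TMM scaling (1.55). The unfolded protein median reversed to 0.011 by median-ratio scaling (−0.15). Read in all cells, which mixes classes, the urea cycle reversed to 0.0068 (−0.18) and cytochrome P450 to 0.048 (−0.15). For NASH-T against Con, lipogenesis was 0.75 by median-ratio scaling, 0.76 by TMM, 0.51 thinned, 0.47 with at least 100 UMIs and 0.50 in all cells (0.67). Cholesterol was 0.70 in all cells (0.81), and the lipid-associated list −0.12 thinned and 0.092, reversed, in all cells (−0.58). For NASH-T against NASH, lipogenesis was −0.78 in all cells and −0.42 in shared clusters (−0.50). In all cells fatty acid oxidation reversed to −0.15 (0.16), cholesterol was −0.87 (−0.64) and the lipid-associated list 0.75 (0.28). The unfolded protein median reversed to −0.0022 by TMM (0.12).

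Counted over all settings, 78 shares of the 5 main classes stayed within counting error, 13 moved and 5 reversed; for smaller classes 90 stayed and 8 moved. Leading lists stayed in 125 cases, moved in 15 and reversed in 1, other lists in 854, 78 and 5. Named genes stayed in 600 cases, moved in 48 and reversed in 0. Counts of list members called stayed in 21 cases and moved in 9. Other results stayed in 55 cases and moved in 14, among them which genes are named in all 3 comparisons with at least 200 UMIs per gene. At a member ratio of 2, cholesterol in NASH-T against Con kept 7 of its 12 higher members and interferon-stimulated genes in NASH-T against NASH 3 of 12.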

Other observations

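The genes, classes and clusters read in this part were chosen after the results had been seen. The interferon-stimulated genes of NASH-T were not confined to the classes in which that list was read: against Con, 4 of 8 measured members were higher and 0 lower in B cell-like cells (median log2 1.02), and 7 of 22 were higher and 1 lower in hepatocyte-like cells (0.46). In NK-like cells 1 of 8 was higher and 1 lower (0.085), and in stellate-like cells 1 of 6 was higher (0.08). IFIT1 was higher by at least 2.26-fold in each of the 5 main classes. Immediate early genes in NASH-T against Con had 9 of 13 members higher in macrophage-like cells (0.71) and 4 of 11 in endothelial-like cells (0.73). Hepatocyte-like cells had 5 higher and 1 lower of 16 (0.33), and T cell-like cells 2 higher and 1 lower of 12 (0.42). In stellate-like cells 2 of 6 were higher (0.38), and in B cell-like cells 0 of 3 (0.13). FOS ran at 48.7, 99.6 and 258 CPM in macrophage-like, 142, 123 and 171 in endothelial-like, 6.75, 4.74 and 21.7 in hepatocyte-like and 241, 25.1 and 1057 in plasma cell-like cells of Con, NASH and NASH-T.

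Of the 817 MMRN1 UMIs in NASH-T endothelial-like cells, 800 lay in cluster 6, led by STAB2 and BMPER, where MMRN1 stood at 1.80, 1.22 and 471 CPM. Cluster 5, led by VWF and FLT1, held MMRN1 at 38.2, 7.46 and 60.8 CPM. The lymphatic gene PROX1 (37.9, 35.3 and 25.3 CPM) was not higher in cluster 6 of NASH-T, with a ratio to Con of 0.668 (0.388 to 1.19). The ratio to Con was 1.57 (1.33 to 1.87) for LYVE1 and 1.19 (0.971 to 1.47) for FLT4, which are lymphatic genes too, LYVE1 being also sinusoidal. FLT4 was found in 31.9%, 28.0% and 33.2% of cluster 6 cells, against 4.76%, 2.67% and 6.45% of cluster 5 cells. With FLT4 so widespread in cluster 6 of every library, these genes do not tell whether cells with MMRN1 are lymphatic. CCL21 had 1 UMI in that cluster of each library, too few to compare. CD274 in cluster 6 stood at 27.1, 8.53 and 43.0 CPM. CD163 in macrophages was lower in NASH within both clusters, at 1059, 186 and 286 CPM in cluster 7 and 1022, 639 and 716 CPM in cluster 10. CD36 was found in 11.8%, 3.70% and 3.27% of thinned macrophage-like cells (18.4%, 7.18% and 7.11% unthinned), against 2.02%, 1.16% and 2.27% of thinned T cell-like cells.

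ANGPTL8, FABP1, RRAD and HAMP were higher in NASH than in Con by at least 2-fold in all 5 main classes, with smallest ratios of 3.78 for ANGPTL8, 3.80 for FABP1 and 2.11 for HAMP. Outside hepatocyte-like cells, free RNA was not separated from expression for FABP1 and HAMP. For RRAD the ratios ran from 16.3 to 28.7 in 4 classes and were at least 2.73 in endothelial-like cells, against 0 UMIs in Con. JCHAIN was higher in NASH-T than in NASH in all 5, with ratios from 3.29 to 7.19. In the cells expected to make it, plasma cell-like cells, JCHAIN stood at 619, 1257 and 2162 CPM. Cholesterol synthesis in NASH against Con had a median of 0.81 (−0.14 to 1.58) in endothelial-like and 1.00 (−0.19 to 2.27) in stellate-like cells, with 4 of 13 and 3 of 8 members higher. In T cell-like cells it was 0.11 (−0.37 to 0.60).

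Mitochondrially encoded RNA was low throughout, at 0.161%, 0.132% and 0.305% of all UMIs. In NASH-T it was higher in NK-like (0.502%, 0.789% and 1.26%), γδ T cell-like (0.434%, 0.785% and 1.15%) and B cell-like cells (0.524%, 0.628% and 1.22%) than in hepatocyte-like cells (0.0981%, 0.0571% and 0.0949%). Within T cell clusters 13, 15 and 16 it was higher in NASH-T alike, at 0.417%, 0.592% and 1.16% in cluster 13, 0.687%, 1.02% and 1.82% in cluster 15, and 0.513%, 0.599% and 1.22% in cluster 16. Plasmacytoid dendritic-like cells made up 0.0833%, 0.250% and 0.123% of cells. Part of macrophage cluster 7 took that name in other settings, where the shares were 2.89%, 3.33% and 1.95% at resolution 0.4, 2.69%, 3.08% and 1.77% at resolution 1.6, and 2.81%, 3.28% and 1.80% with doublets kept. The main clusters held mast- or basophil-like cells at 0.375%, 0.417% and 0.224% and proliferating cells at 0.292%, 0.155% and 0.179%. Mixed clusters had median depths of 6761, 6499.5 and 6275 UMIs, above the 4210, 3868 and 4045.5 of hepatocyte-like cells.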
